A study of Mus musculus with 2 samples.

How the data were processed

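Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out in SCOS#2, a mouse cell line from an EWS-FLI1-induced osteosarcoma model. EWS-FLI1 is the fusion of the RNA-binding protein EWS with the ETS-family transcription factor FLI1 and is the characteristic fusion of Ewing sarcoma. Per the labels' protocols, cells were kept in doxycycline at 2 µg/ml for 72 h, sonicated chromatin was precipitated with a monoclonal antibody against the HA tag, and libraries were built with an Illumina TruSeq ChIP kit. The series analysed here holds 1 ChIP library and 1 input library, without replicates, and only the ChIP sample carries a processed file: a peak list in BED format without a header.

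Cutadapt, Bowtie2 2.2.0 and the mouse build mm9 are named in the submitters' processing notes. The name of the deposited file names MACS as the peak caller and carries the word input. The MACS version, its cutoff, the handling of duplicate reads and any removal of repeated regions are not given in the sources used here. The list gives a position, a name and a score per peak. The score is the authors' own value from the peak caller, deposited without a stated scale. Read totals of the 2 libraries are not in this list, so the sequencing depth is unknown.

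The scale of the deposited score was examined from the values themselves, after the data had been seen. The score was read as −10 log10 of the Poisson probability of at least a given whole number of reads, over a background that is constant up to a window and then proportional to peak width. The commonest score was set to each count from 3 to 15 in turn, and the background per base was taken as the median over slightly wider peaks. With a count of 7, 1867 of the 2563 peaks (72.8%) lay within 0.02 of a whole-number step. The highest share for any other starting count was 4.99%, and the highest share over 20 sets of scores shifted at random by up to 2 was 1.29%. The fitted background was 1 read per 276.4 bp, with a window of 352 bp. On this reading a score of 30 equals a p of 0.001 and a score of 50 a p of 1e-05. Counts given below as implied reads come from this reading for peaks that lay on a step, and are 1 lower if the caller counted a strictly larger tail.

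Peak starts were converted to 1-based coordinates of mm9. Widths, scores and positions were summarised over peaks. The share of peaks per chromosome was compared with that chromosome's share of the summed spans (first peak start to last peak end) by an exact binomial test with Benjamini-Hochberg adjustment over the 23 chromosomes and contigs with at least 10 peaks. The other 5 contigs or chromosomes, with 14 peaks in all, were not tested. Shares carry 95% Wilson intervals, which cover counting error only. These intervals and the binomial test treat peaks as independent, so with clustered peaks the intervals are too narrow and the p-values too small. Peak clustering was the share of peaks with another peak centre within 10 kb, compared with 1000 uniform placements of the same number of peaks within each span. These placements ignore unmappable sequence, so they spread peaks more evenly than a caller could. Width and score were compared by Spearman's and Pearson's (log10) coefficients, and the widths of the 25% of peaks with the highest and the 25% with the lowest scores through the difference of medians, each with 100000 permutations, two-sided. Peaks of 1 library are not replicates: every p-value compares this list with a random arrangement of it, not a condition with another.

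Alternatives fixed before the data were examined were a score of at least 100, scores above the median, autosomes only, merging of touching peaks, removal of the 1% widest peaks, neighbour distances of 5 and 50 kb, and other score classes. Added afterwards were a score of at least 50, removal of unplaced contigs, and removal of megabases with 10 or more peaks. The rule fixed beforehand names the 20 peaks with the highest scores, the 5 groups of neighbouring peaks with the most members, and the widest peak. Tests of gene position, sequence motifs and gene lists had been planned for an mm9 genome and annotation. The gene table at hand is of another build (GRCm38) and was not used here, so peaks are named by position.

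The tests were tried on simulated data. Of 200 planted neighbour pairs the clustering count recovered 392 additional peaks with a neighbour, with a one-sided p of 0.005, the smallest that the 200 placements of that trial allow. Chromosomes simulated at a reduced density (0.5 of the others) were called low in 99.8% of 400 cases, and 6 of 100 lists without any difference gave a call. The simulated lists held independent peaks, so these rates do not cover clustered peaks. For the score steps, the simulated starting count of 7 and background of 1 read per 300 bp were both recovered, and 99.6% of the peaks on steps received the right count. The simulated scores came from the same formula as the fit. This trial therefore checks the fitting only, and not whether the deposited scores follow that formula. Computations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and figures used matplotlib 3.10.9.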

Results

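ChIP-seq for HA-tagged EWS-FLI1 was carried out in the SCOS#2 osteosarcoma line after 72 h in doxycycline. The question addressed by the assay was where in the mouse genome the induced fusion protein lies. The data consist of 1 peak list from 1 ChIP library; an input library of the same treatment completes the series. There are no replicates and no uninduced sample in the series analysed here, so no peak carries a replicate error and no binding change on induction could be measured.

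The list held 2563 peaks on 28 chromosomes and contigs of mm9, covering 2.03 Mb. Most peaks were narrow and had scores near the lowest of the list. The median width was 720 bp (quartiles 590 and 912.5 bp, range 205 to 6166 bp), and 2099 peaks (81.9%) were narrower than 1 kb. The median score was 34.6 (quartiles 32.2 and 39.9) on a scale that started at 30.01. A score of 50 was reached by 203 peaks (7.92%, 95% Wilson interval 6.94 to 9.03%), a score of 100 by 6 peaks (0.234%, 0.107 to 0.51%), and a score of 150 by 3 peaks. On the reading given above, a score of 30 is a Poisson p of 0.001 for a single region, without correction for the many regions of a genome. No false discovery rate comes with the list, so the number of chance calls in it is unknown and may be large. For the 1867 peaks whose scores fell on whole-read steps, the implied support was a median of 10 reads (quartiles 9 and 11, range 7 to 35), a median of 3.97 times the background expected for their width. In 94% of these peaks the implied support was 15 reads or fewer. The other 696 peaks have no implied count, and wide or high-scoring peaks are more common among them: 48.8% of the peaks wider than 1 kb lay on steps against 78.1% of the others, and 57.1% of those with a score of 50 or more against 74.2%.

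The 3 highest scores of the list lay at 2 places. On chromosome 19, the peak at 37025452 to 37026003 had the highest score of the list, 230.72, with 29 implied reads over 2.00 expected (14.5-fold). A second chromosome 19 peak at 37030537 to 37031383 scored 161.86, with 27 implied reads (8.81-fold), and its centre lay 5232 bp from the first. Together with a further peak they formed a group of 3 peaks within 7767 bp (37025452 to 37033218). On chromosome 17, the peak at 4625876 to 4626863 scored 221.58, with 35 implied reads over 3.58 expected (9.79-fold); its nearest neighbour lay 542265 bp away. The next score in the list was 108.9, on chromosome 4 at 129634662 to 129635270. It was followed by 108.03 on chromosome 11 (108872856 to 108873529) and 100.01 on chromosome 1 (78570253 to 78571074). These 6 peaks were all narrower than 1 kb.

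The other 14 of the 20 highest scores ran from 98.14 to 75.86. They lay at 8850048 to 8851691 on chromosome 14 (98.14), 139147214 to 139149148 on chromosome X (93.63), 21504799 to 21506353 on chromosome 2 (91.98) and 13952816 to 13953612 on chromosome 13 (89.92). Chromosome 17 added a peak at 39979700 to 39985865 (86.58), which at 6166 bp was also the widest of the list, and one at 29242599 to 29246081 (78.99). Chromosome 6 held peaks at 47714618 to 47716381 (83.16) and 146398038 to 146398893 (82.38). Chromosome 4 held peaks at 122387528 to 122389447 (78.98) and 146158557 to 146160176 (75.86). The remaining ones were at 19957397 to 19961438 on chromosome 8 (78.04), 67037885 to 67039203 on chromosome 7 (76.3), 112073433 to 112074835 on chromosome 1 (76.26) and 125187369 to 125189022 on chromosome 14 (76.26). Among the 20 peaks, 8 were narrower than 1 kb and 3 were wider than the 99th percentile of all widths. Among the 14 peaks, implied counts exist only for those on X, at 146398038 on chromosome 6, at 112073433 on chromosome 1 and at 125187369 on chromosome 14. The widest peak has none, as its score lay off the steps. The gene, exon or intergenic context of these positions, and their overlap with repeated sequence, was not analysed here.

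Higher-scoring peaks were wider. The 25% of peaks with the highest scores had a median width of 960.5 bp (quartiles 734.8 and 1217.5 bp, n = 640 peaks), against 658 bp (538 and 784.2 bp, n = 640) in the 25% with the lowest scores. The difference of 302.5 bp exceeded that of every permutation (two-sided permutation p = 1e-05, the smallest they can give). Across the 2563 peaks, which are not independent replicates, Spearman's rho of width and score was 0.36 and Pearson's r of their logarithms 0.39 (permutation p = 1e-05 for both, also after adjustment for 2 relations). Among the 203 peaks with a score of 50 or more, Pearson's r was 0.0972 (permutation p = 0.166) and Spearman's rho 0.21 (permutation p = 0.00263). On the reading given above, the score itself is computed from a background that depends on width. Permutations that break any link of width and score are therefore not a neutral reference, and the relation may partly reflect how the score is built.

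**Figure D1:**
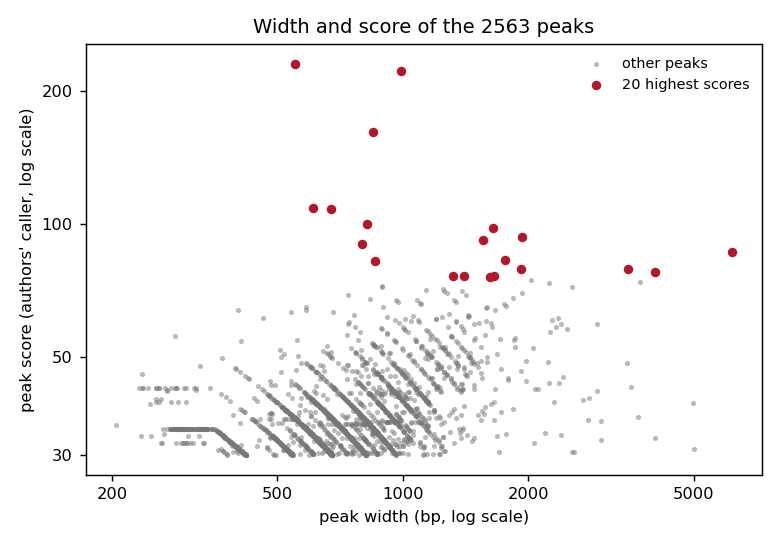
Peak width in bp (x, log scale) against the score from the authors' peak caller (y, log scale), 1 point per peak, with the 20 highest scores in red. The 3 peaks above a score of 150 are all narrower than 1 kb, and many of the weaker peaks fall on descending lines; 1867 of the 2563 peaks lie within 0.02 of the score computed for a whole number of implied reads.

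Peaks were spread over all chromosomes, but chromosome 11 held far fewer than its length would give. It carried 44 peaks, 1.73% of the tested list (95% Wilson interval 1.29 to 2.31%), against 4.37% expected from its span, a ratio of 0.395 (0.295 to 0.529; exact binomial test, adjusted p = 2.71e-12). Mouse chromosome 11 is known as one of the most gene-dense chromosomes. Chromosome 9 was also low, with 78 peaks and a ratio of 0.69 (0.555 to 0.858; exact binomial test, adjusted p = 0.00238). Chromosome 4 was high, with 203 peaks and a ratio of 1.36 (1.19 to 1.55, exact binomial test, adjusted p = 9.32e-05). The exact test counts peaks as independent, but peaks were clustered, with 44 of those on chromosome 4 in crowded megabases. The p-values and intervals therefore overstate the certainty. By the same exact test, the other 17 of the 20 (numbered chromosomes and X) had ratios between 0.702 (chromosome 19, adjusted p = 0.0645) and 1.19 (chromosome 16, adjusted p = 0.199), and none passed the test with all peaks. Density on X was 0.958 peaks per Mb (156 peaks, ratio 0.975).

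The calls on chromosomes 4, 9 and 19 depended on which peaks were kept. Without the megabases that held 10 or more peaks, the ratio of chromosome 4 was 1.13 (0.967 to 1.31; exact binomial test, adjusted p = 0.271). Among peaks above the median score, the ratio of chromosome 9 was 0.938 (exact binomial test, adjusted p = 0.782), whereas that of chromosome 11 was 0.413 (0.276 to 0.616, adjusted p = 5.27e-06) and that of chromosome 19 passed the test at 0.526 (adjusted p = 0.0355). Among the 203 peaks with a score of 50 or more, none of these chromosomes passed the test. The ratios were 0.567 for chromosome 11 (0.243 to 1.3), 0.447 for chromosome 9 (0.174 to 1.12), 1.01 for chromosome 4 (0.586 to 1.72) and 1.11 for chromosome 19 (0.475 to 2.53), with intervals too wide to show a difference at this number of peaks.

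**Figure D2:**
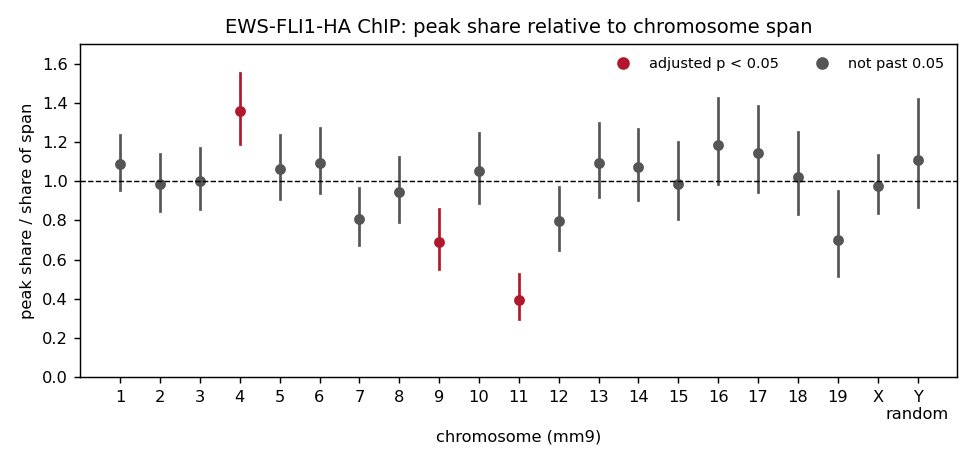
Share of peaks on each mm9 chromosome divided by its share of the summed spans (y), with 95% Wilson intervals as vertical lines; the dashed line marks a ratio of 1, and red marks an adjusted p below 0.05. Chromosome 11 lies lowest, at 0.395, chromosome 9 is at 0.69 and chromosome 4 at 1.36; the contigs chr1_random and chr8_random, at 33.5 and 18, are left out for scale.

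Sequence that mm9 does not place on the assembled chromosomes held 104 peaks (4.06%, 95% Wilson interval 3.36 to 4.89%) on 7 contigs. Of these, 61 lay on the unplaced part of chromosome Y, at 1.09 peaks per Mb, a density that did not differ from its span (ratio 1.11; exact binomial test, adjusted p = 0.637). The unplaced contigs of chromosomes 1 and 8 were far denser, with 18 and 13 peaks at 32.9 and 17.7 peaks per Mb. By the exact binomial test, their ratios were 33.5 (adjusted p = 2.84e-20) and 18 (adjusted p = 9.17e-12). Because these short spans were set by the first and last peak themselves, the ratios are upper estimates. Peaks on these contigs were also wide, with medians of 1042.5 bp and 1382 bp.

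Peaks lay closer together than random placement gave. Another peak centre lay within 10 kb of 317 peaks (12.4%, 95% Wilson interval 11.1 to 13.7%), 5.03 times the median of random placements (2.46%, range 1.41 to 3.71% over 1000 placements; one-sided permutation p = 0.001, the smallest they can give). Chaining neighbours at 10 kb gave 2246 single peaks, 125 pairs, 18 groups of 3, 2 groups of 4 and 1 group of 5. The group of 5 was on chromosome 4 at 146231634 to 146248614, with a highest score of 60.74. The groups of 4 lay on chromosome 4 at 146147161 to 146160809 (highest score 75.86) and on chromosome 8 at 19727457 to 19741889 (73.61). The next by highest score were the chromosome 19 group with the strongest peak and a group of 3 on chromosome 9 at 109263716 to 109268510 (63.88).

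A few megabases were crowded. The megabases from 145 to 146 and from 146 to 147 Mb of chromosome 4 held 20 and 24 peaks, those from 65 to 66 and from 66 to 67 Mb of chromosome 13 held 11 and 13, and that from 19 to 20 Mb of chromosome 8 held 11. The highest count of any megabase over 1000 random placements was 10, with a median of 6. With the crowded megabases of the unplaced contigs, 7 megabases held 107 peaks (4.17%), with a median width of 1005 bp against 713 bp elsewhere and a median score of 38.3 against 34.5. Without these megabases, 10.8% of the remaining 2456 peaks still had a neighbour within 10 kb, against at most 4.28% in random placements.

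**Figure D3:**
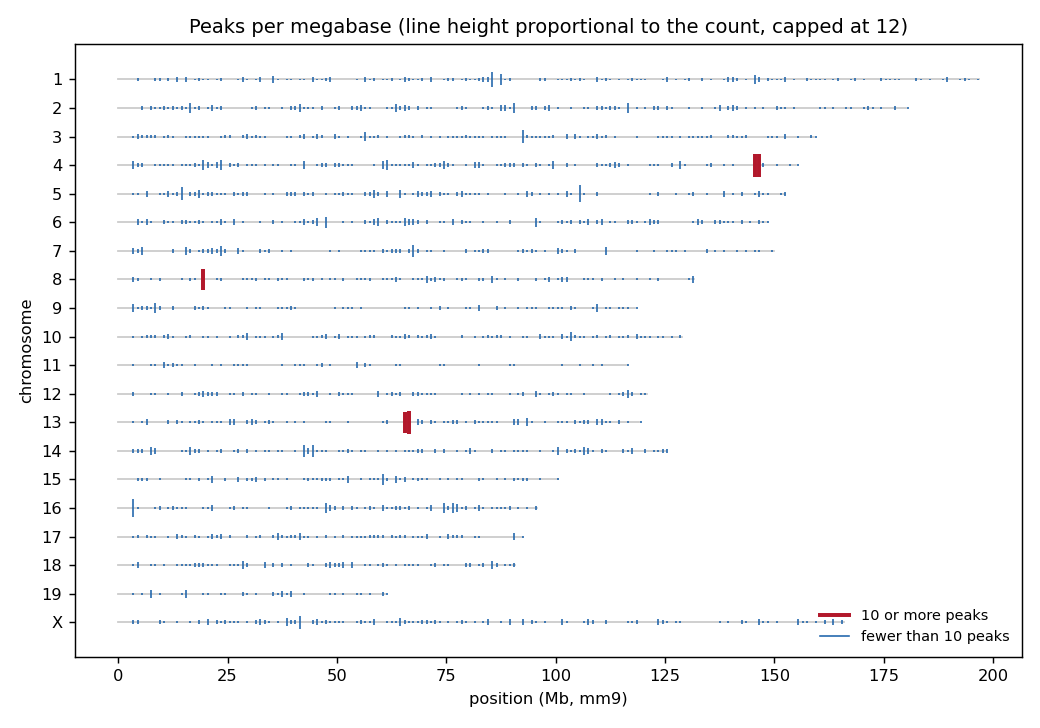
Number of peaks in each megabase of the numbered chromosomes and X (x, position in Mb of mm9; 1 row per chromosome), drawn as vertical lines whose height is proportional to the count, capped at 12. Red lines mark the 5 megabases with 10 or more peaks, which lie on chromosomes 4, 8 and 13; the sparse row of chromosome 11 holds 44 peaks.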

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

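The score of at least 50, the removal of unplaced contigs and the removal of megabases with 10 or more peaks were chosen after seeing the data. The closeness of peaks lay above every random placement in 5 of 7 alternatives. Shares were 8.59% to 11.55% at 10 kb, 9.75% at 5 kb (placements up to 2.575%) and 22.6% at 50 kb (placements up to 12.88%). At a score of at least 50 it was 2.46% (permutation p = 0.015), within the range of the placements (up to 2.96%), and at a score of at least 100 it rested on 2 of 6 peaks and equalled the highest placement (33.3%). The wider peaks of the top score class kept their direction and their side of the threshold in all 3 alternatives. A score of at least 100 left 6 peaks, with a median width of 748 bp, a median score of 135.38 and 0 chromosomes called. It turned Spearman's rho to -0.0857 (exact permutation p = 0.919), lowered Pearson's r to 0.11 (exact permutation p = 0.858), raised the chromosome 11 ratio to 3.82 (1 peak) and put the contigs chr1_random and chr8_random at 0, all with too few peaks to test. Scores above the median kept 1280 peaks (median width 829 bp, median score 39.9). A score of at least 50 kept 203 peaks (median width 1149 bp, median score 56.6), called 1 chromosome or contig, and lowered Pearson's r to 0.0972. With all peaks 5 were called, against 3 with autosomes only, 3 without unplaced contigs and 2 without megabases of 10 or more peaks. In each of these settings the contigs chr1_random and chr8_random were not tested, and in the last chromosome 4 also lost its call. No deposited peaks touched, so merging moved nothing. The alternatives for gene position, motifs and gene lists were not run, because no mm9 genome or annotation was used here. No paired analysis was possible because each group has 1 sample. With 1 library, and a median of 10 implied reads over the 1867 peaks that have a count, the list does not show how repeatable the weak peaks are. It also does not show which of them are binding sites, and absence from the list does not show absence of binding.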

Other observations

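Along the chromosomes, peak counts differed between segments in a way not described above. Over the numbered chromosomes and X, the first of 10 equal segments of the spans, next to the centromere in the acrocentric mouse chromosomes, held 290 peaks against 245.7 expected (11.8%, 95% Wilson interval 10.6 to 13.1%; exact binomial test, adjusted p = 0.0171 over the 10 segments). Segments 8 and 9 held 206 (exact binomial test, adjusted p = 0.0237) and 192 peaks (adjusted p = 0.00214). The last segment, which contains the crowded megabases of chromosome 4, held 249. Each span began and ended at a peak, so the first and last segments held a peak of every chromosome by construction. The even expectation of 245.7 is therefore too low for the end segments and too high for the others. The p-values of the first segment and of segments 8 and 9 are thus too small, and no test with a corrected expectation was run. The segment tests, and those below except the neighbour gaps, the local background of close peaks, the parts of chromosome 11 and the step from the score 31.92, were chosen after the values had been seen. The chromosome 11 ratio above the median score was among the alternatives fixed beforehand, and only its use to weigh an explanation was chosen afterwards.

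Many peaks shared exactly the same score: 1966 of 2563 peaks (76.7%) had a score that another peak also had. The deposited scores were rounded and crowded near the cutoff (median 34.6, upper quartile 39.9), so much of this sharing could arise by rounding alone. How much was not computed. The commonest score, 34.47, was held by 98 peaks, against 25 for the next commonest. Small whole read counts over 1 common background are a candidate explanation, since 72.8% of the peaks lay on whole-read steps against at most 4.99% for other starting counts. For a second, higher background 1 step was tested: from the score 31.92 with a count of 7, the next score was computed as 39.56, which 7 peaks had. Below the lowest step lay 28 narrow peaks. Of these, 82.1% (64.4 to 92.1%) implied a local background within 0.05 of a whole number of reads per 10 kb, where chance gives 10%. However, 18 of them shared the value 40, the background behind the score 31.92, so both tests rest largely on the same peaks. The interval counts these peaks as independent and is therefore too narrow. Whole-number values could arise from local backgrounds counted without a scaling factor between ChIP and input, or from the ChIP library itself. The list alone leaves open which.

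Peaks lay closer together than in random placements, and the tables argue against each of 2 technical explanations acting alone as the whole cause. Without the crowded megabases the share with a neighbour was 10.8%, above every placement. Megabases with up to 9 peaks were kept, however, against a median highest count of 6 in random placements. The placements also ignore unmappable sequence, and the 2 explanations were not tested together. Milder crowding, or both explanations combined, is therefore not excluded. Splitting of 1 broad region by the caller would leave short gaps, but only 32.7% (26.2 to 40.1%) of the 171 neighbouring pairs had edges under 1 kb apart, and the median gap was 1874 bp. Whether close peaks lie where the local background was raised stays open: 59.6% (54.1 to 64.9%) of them followed the genome-wide background against 74.7% of the others (two-sided Fisher's exact test, adjusted p = 1.21e-07), but among peaks of at most 1 kb the values were 72.8% and 78.8% (adjusted p = 0.0719). Close peaks come in pairs and groups, which Fisher's test counts as independent peaks. No biological explanation was tested, since the series has 1 ChIP group, and binding of neighbouring sites remains possible alongside repeated sequence.

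In the 7 crowded megabases, 18.7% of the 107 peaks (12.4 to 27.1%) followed the genome-wide background, against 75.2% elsewhere (two-sided Fisher's exact test, adjusted p = 3.57e-32), and among peaks of at most 1 kb the shares were 37.7% and 79.2% (adjusted p = 4.41e-10). The 107 peaks come from only 7 megabases, and neighbouring peaks may share a local background. Fisher's test counts each peak as independent, so these p-values are far too small. Of the 203 peaks with a score of 50 or more, 40 (19.7%) had any peak within 10 kb, against at most 8.37% when the other peaks were placed at random.

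Peak density differed between chromosomes. Chromosome 4 had a ratio of 1.13 (0.967 to 1.31) without its crowded megabases, but the removal was set by the same peak counts and took 44 of its 203 peaks, so a fall was built in and the origin of its excess stays open. A single empty segment does not account for the deficit on chromosome 11: its 3 equal parts had 19, 17 and 8 peaks, and the highest of their ratios was 0.512 (0.328 to 0.798). Peaks at or below the median score do not account for it alone, since above that score the ratio was 0.413 (0.276 to 0.616). The median score of that upper set was 39.9, still near the lowest score of 30.01, so an effect of the cutoff is not excluded. Whether the 203 peaks with a score of 50 or more share the deficit stays open, because their ratio of 0.567 (0.243 to 1.3) includes both the value for all peaks and 1. A lower copy number of the chromosome in this line, or a base composition that the library or the caller disfavours, are untested alternatives, since neither the reads nor the sequence were used here.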
